A study of Mus musculus with 52 samples.

How the data were processed

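MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured by small RNA sequencing in the white fat around the gonads of C57BL/6 mice aged 6 months. The mice were wild type (WT) or carried, in 1 copy, a huntingtin knock-in allele named by its CAG repeat length (Q20, Q80, Q92, Q111, Q140 or Q175). Per the labels' protocols, tissue was frozen on dry ice, total RNA was taken with a Qiagen miRNeasy kit and Illumina libraries were made from an enriched RNA subfraction. CASAVA 1.8.2 is named in the submitters' processing notes. The aligner, the genome build, the miRBase release and the counting program are not given in the sources used here.

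The authors deposited a table of estimated counts with 1187 miRNA precursors and 52 libraries, in which 89.1% of the values were whole numbers within a tolerance of 1e-04. The estimated counts were rounded to whole numbers before any count test. The tests had been planned for whole counts. The authors also deposited a table of RPKM values (counts scaled to precursor length and library total) for the same precursors and libraries. Each precursor's length was recovered from the ratio of both tables in the 263 precursors with at least 100 estimated counts in a library, and came out whole within 0.01 in all 263, from 49 to 147 nucleotides. All columns were matched to a sample by the library identifier in its labels.

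The precursors are named by miRBase accessions alone, and the files do not pair these accessions with miRNA names. No name was therefore given to any precursor, no coordinates are given, and the 22 miRNA lists with 239 members that had been fixed beforehand, tissue markers among them, were matched to 0 precursors and not tested. At most 2 accessions that rose and 2 that fell are printed for a comparison. They are those with the largest log2 fold change among precursors with an adjusted p under 0.05 and a mean of at least 10 CPM (counts scaled to library size) in the libraries fitted, or, where none passed, the precursor with the lowest p. This shortens the rule fixed beforehand, which took up to 10 in each direction. In 26 sets of precursors, 68 in all, every library held identical values. Reads shared between near-identical copies can give this, as can coincidence in sets whose counts are very few, and which of these applies was not tested. A call in such a set is uncertain, and precursors with nearly the same values are not in this count.

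Groups are genotype and sex, 14 in all with 3 or 4 libraries each. The labels do not state outright that the libraries of a group come from separate animals, so a p-value may measure only the spread between these libraries. Of the 72 pairs of libraries within a group, the closest differed by a chi-square of 26.2 per degree of freedom, so none was counted as a duplicate. The labels give library numbers in 2 series and the column names a lane token. All WT and Q175 libraries belong to 1 series, all in lane 5 (15 libraries, the lane 5 series). The other genotypes belong to the other series, with 23 libraries in lane 1, all Q111 libraries among them, and 14 in lane 3 (the lane 1 and 3 series). A comparison of WT or Q175 with Q20 cannot be told apart from a difference between these series. The housing labels place WT and Q20 mice together and the other genotypes with their own kind. A comparison of Q175 with WT, or of a longer allele with Q20, can therefore not be told apart from a difference in housing.

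Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM scaling) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, on precursors with at least 10 counts in at least 7 of the libraries fitted. Q175 was compared with WT in the 15 libraries of the lane 5 series, with sex as a covariate. Q80, Q92, Q111 and Q140 were compared with Q20, and a slope per 100 repeat units was fitted, in the 37 libraries of the lane 1 and 3 series with sex as a covariate. Females were compared with males over all 52 libraries with genotype as a covariate. Interactions of sex with genotype, and Q20 against WT and Q175 against Q20, were fitted likewise. CPM values use the TMM library sizes. Principal components were computed on log2 CPM with a prior count of 2.

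Alternatives, fixed before the data were examined unless said otherwise, were DESeq2 1.42.0 and its size factors, no filter, a minimum of 50 counts, limma 3.58.1 on log2(RPKM + 1), removal of the 5 most abundant precursors, 1 surrogate variable from sva 3.50.0, a replicate block, each sex alone, the lane as a covariate and each library left out in turn. Fits without the 15 libraries above 5 on principal component 1, fits without 2 Q140 libraries and a Q175 fit over all 52 libraries were added after seeing the data.

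The count test was tested on simulated data with 200 changed precursors of known size among those detected in each comparison, and only part of these passed the filter. Each precursor was drawn independently, without variation shared between precursors of a library. The shares of recovered and false calls therefore need not hold for the real libraries. For Q175 against WT, 28 of 32 tested precursors with a simulated log2 change of 1 and 39 of 41 with a change of 2 were recovered, and 2 of 69 calls were false. False calls were above the threshold of 0.05 as a share of calls for Q80 against Q20 (5 of 56), sex (6 of 74), the slope (4 of 64) and the sex by Q175 interaction (2 of 39). For Q140 against Q20, 19 of 30 and 42 of 48 were recovered. For the slope, with the change set over the full range of repeat lengths, 25 of 35 and 35 of 38 were recovered. For the sex by Q175 interaction, 17 of 44 and 20 of 24 were recovered. For the sex by repeat length interaction, 4 of 39 and 14 of 32 were recovered.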

Results

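The data cover miRNA precursors in gonadal white fat of an allelic series of huntingtin knock-in mice, in which longer CAG repeats model Huntington's disease. There were 8 libraries of Q175, Q20 and Q80 and 7 of WT, Q92, Q111 and Q140, from 25 females and 27 males. Groups of 1 genotype and sex held 4 libraries, except WT, Q111 and Q140 females and Q92 males with 3. Total estimated counts per library ran from 1812067 to 5487948, with a mean of 3800195 ± 795919 (SD, n = 52). Of 1187 precursors, 1014 had a count in at least 1 library and 173 had none. The 5 most abundant precursors took 60.2% ± 4.02 (SD, n = 52) of a library's counts. The highest, MI0000221, took 21.1% on average, and MI0000257 took 15.3%.

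The libraries differed most along an axis on which many male samples stood apart. Principal component 1 held 45.6% of the variance, with a mean score of 6.72 ± 13.7 in males (SD, n = 27) and -7.26 ± 4.91 in females (SD, n = 25). The score was above 5 in 14 males and 1 female library, Q140_F replicate 2. Females of every other group lay between -10.8 and -3.88. The difference of 13.98 between the sexes passed a 2-sided permutation test (p = 0.00003). Within the lane 5 series the difference was 13.4 (exact permutation p = 0.00451) and within the lane 1 and 3 series 14.3 (permutation p = 0.00042). Principal component 2 held 15.4% and parted the lane 5 series (-10.4 ± 1.75, SD, n = 15) from the lane 1 and 3 series (4.20 ± 3.35, SD, n = 37).

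**Figure D1:**
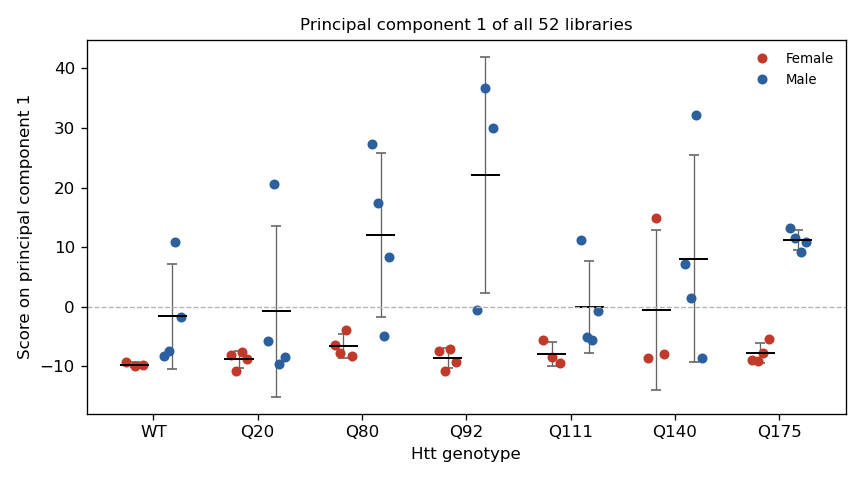
Score on principal component 1 (vertical axis, no unit) of the 52 libraries by huntingtin genotype (horizontal axis) and sex; points are libraries, bars the mean and error bars 1 SD. The 4 Q175 males lie between 9.12 and 13.2, and scores reach 36.7 in Q92 males.

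The comparison of Q175 with WT asked which miRNAs differed in fat with the longest repeat, though housing differed between these groups as well. MI0000248 was higher in Q175, at 157 ± 203 CPM (SD, n = 8) against 3.96 ± 1.75 in WT (SD, n = 7), a log2 fold change of 4.69 (SE 0.90, adjusted p = 0.0282). MI0000224 was higher as well, at 1163 ± 1547 CPM against 117 ± 82.3 (log2 2.63, SE 0.66, adjusted p = 0.0409). MI0000248 averaged 283 ± 228 CPM in Q175 males (SD, n = 4) and 31 ± 42.2 CPM in Q175 females (SD, n = 4). The edgeR interaction with sex gave no call. Its log2 difference, females minus males, was -3.31 for MI0000248 (unadjusted p = 0.027, adjusted p = 0.744). For MI0000224 it was -2.66 (unadjusted p = 0.018, adjusted p = 0.676), so a difference between the sexes is not excluded. MI0014108 was lower, at 25.1 ± 3.96 CPM in Q175 and 45.0 ± 13.5 in WT (log2 -0.82, SE 0.18, adjusted p = 0.0282), and MI0000595 was lower, at 49.96 ± 4.99 and 79.8 ± 21.3 CPM (log2 -0.67, SE 0.16, adjusted p = 0.0282). Each of these precursors lay on its side of the WT median in 8 of 8 Q175 libraries. Single omissions lost the call of MI0000248 in 5 of 15 fits and that of MI0000224 in 10 of 15. The calls of MI0014108 and MI0000595 were each lost in 8 of 15. Fitted over all 52 libraries, Q175 gave 0 higher and 8 lower calls against WT. Some males of other genotypes above 5 on principal component 1 held more of both, with 3906 and 11776 CPM in Q140_M replicate 3. Q80_M replicate 4, also above 5, held 7.64 and 57.3 CPM.

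In all, 14 of 308 precursors passed edgeR's test, 2 higher and 12 lower in Q175, with a median absolute log2 change of 0.57. Fitted alone, females gave 0 calls among 247 precursors (25 with an unadjusted p under 0.05) and males 1 among 271 (51 with an unadjusted p under 0.05). The 12 lower precursors, chosen in the fit of both sexes, lay lower by a median log2 of 0.56 there, 0.44 in females and 0.42 in males, with 11 measured in each sex. The 2 higher ones had a median of 3.66, 2.04 in females and 5.15 in males. Q175 males scored 12.8 higher than WT males on principal component 1 (exact permutation p = 0.0571, 2-sided, 4 against 4), and Q175 females 1.93 higher than WT females (exact permutation p = 0.114). The count of 14 became 0 without the libraries above 5 on that component, where 0 Q175 males are left, 34 with DESeq2 (15 higher, 19 lower), and between 0 and 37 when 1 library was left out.

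The 4 longer alleles in the lane 1 and 3 series were each set against the same Q20 libraries. MI0004133 was lower in 3 of them: 78.5 ± 15.7 CPM in Q20 (SD, n = 8), 50.2 ± 8.77 in Q80 (SD, n = 8), 46.7 ± 12.5 in Q92 (SD, n = 7) and 48.9 ± 9.38 in Q140 (SD, n = 7). Its log2 fold changes were -0.70 (SE 0.16, adjusted p = 0.0451), -0.81 (SE 0.17, adjusted p = 0.0110) and -0.73 (SE 0.17, adjusted p = 0.0440), below the Q20 median in 8 of 8, 7 of 7 and 7 of 7 libraries. Single omissions lost the call in 20 of 37 fits for Q80, 10 of 37 for Q140 and 0 of 37 for Q92. In Q111 MI0004133 stood at 53.4 ± 10.3 CPM (SD, n = 7) and did not pass. These values share the Q20 controls and so are not independent of one another. Housing also set the longer alleles apart from Q20, so repeat length and housing cannot be told apart here.

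**Figure D2:**
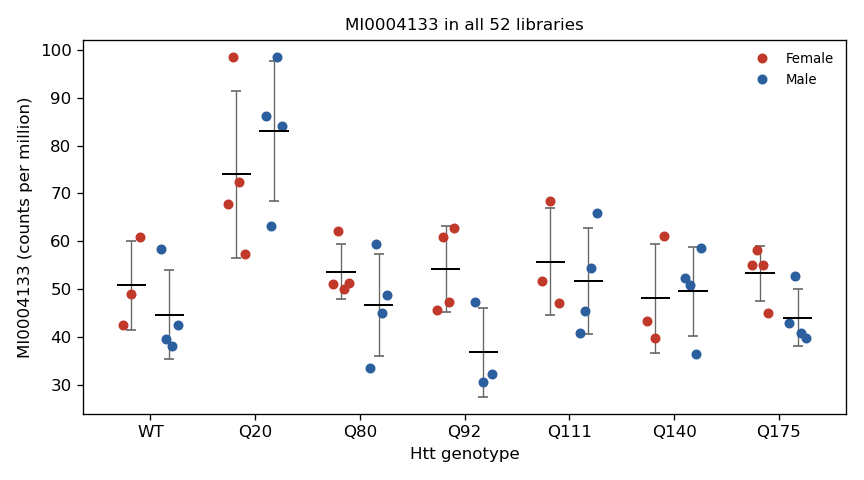
MI0004133 in CPM (vertical axis) in the 52 libraries by huntingtin genotype (horizontal axis) and sex; points are libraries, bars the mean and error bars 1 SD. Q20 libraries have a mean of 78.5 CPM, and the means of Q80, Q92, Q111 and Q140 lie between 46.7 and 53.4 CPM. The means of WT and Q175, in the other series, are 47.3 and 48.7 CPM.

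Q80 differed from Q20 in 5 of 345 precursors, 2 higher and 3 lower. MI0004702 was higher in Q80, at 17.8 ± 4.03 CPM (SD, n = 8) against 10.8 ± 4.77 (SD, n = 8), with a log2 fold change of 0.71 (SE 0.19, adjusted p = 0.0483). MI0000580 was lower, at 210.0 ± 28.5 against 282.8 ± 53.1 CPM (log2 -0.46, SE 0.11, adjusted p = 0.0468). Single omissions lost the call of MI0004702 in 31 of 37 fits and that of MI0000580 in 25 of 37. The count of calls was 0 with the lane as a covariate and 9, all higher, with limma on RPKM, a scale on which the median of all precursors moved by 0.24.

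Q92 differed from Q20 in 14 precursors, 8 higher and 6 lower. MI0023705 averaged 74.3 ± 171 CPM in Q92 (SD, n = 7) and 0.293 ± 0.606 in Q20 (SD, n = 8; 7 counts in all), with a log2 fold change of 7.08 (SE 1.74, adjusted p = 0.0323) that rests on few libraries, since the Q92 median was 0.599 CPM. MI0000820 averaged 34.7 ± 44.3 against 3.55 ± 2.996 CPM (log2 3.25, SE 0.95, adjusted p = 0.0477), above the Q20 median in 5 of 7 Q92 libraries. This call was lost in 29 of 37 single omissions, and the log2 change was 1.64 without Q92_M replicate 2. MI0000170 was lower, at 277 ± 31.7 against 483 ± 219 CPM (log2 -0.83, SE 0.25, adjusted p = 0.0477), a call lost in 34 of 37 single omissions. Without the libraries above 5 on principal component 1 the count was 5, and with 1 surrogate variable it was 1.

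Q111 gave 0 calls against Q20 by edgeR, with 56 precursors at an unadjusted p under 0.05, 0 calls by DESeq2 and 2 by limma on RPKM. The lowest p belonged to MI0000550, with 16098 ± 3183 CPM in Q111 (SD, n = 7), 21882 ± 3582 in Q20 (SD, n = 8) and an adjusted p of 0.173. Without Q111_F replicate 2 there were 2 calls. Q140 gave 1 call against Q20, MI0004133 above. That call was lost without Q140_F replicate 2 and Q140_M replicate 4, which left 0 calls, and DESeq2 gave 17 (15 higher, 2 lower).

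The slope over repeat length asked whether miRNAs moved in step with the CAG number from Q20 to Q140. MI0004133 was the 1 precursor of 345 that passed, with a log2 slope of -0.60 per 100 repeat units (SE 0.14, adjusted p = 0.0300); 56 had an unadjusted p under 0.05. The slope rested on Q20: among Q80, Q92, Q111 and Q140 it was 0.12 (adjusted p = 0.994). WT libraries, in the other series, averaged 47.3 CPM of MI0004133, near the longer alleles rather than Q20. The slope of MI0004133 was fitted without WT. That slope also lost its call with the lane as a covariate, at -0.54 (adjusted p = 0.0869), and DESeq2 gave 6 calls, 5 with a positive slope. The call of MI0004133 for the slope was lost in 13 of 37 single omissions.

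The Q175 changes were set against the slopes of the separate lane 1 and 3 libraries to ask whether both moved the same miRNAs. Across 306 precursors, which are not independent replicates, log2 changes in Q175 and slopes correlated with Pearson's r = 0.479 and Spearman's rho = 0.183. Of 100 labellings of the lane 5 libraries within sex, the real one included, 19 gave as large a Pearson's r (p = 0.19) and 51 as large a rho (p = 0.51), so the relation did not exceed what relabelled libraries gave. Without the libraries above 5 on principal component 1, r was 0.144.

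Sex was the factor with the most calls within a library series. MI0000553 was higher in females, at 709.9 ± 229.8 CPM (SD, n = 25) against 127.6 ± 193.7 in males (SD, n = 27), with a log2 fold change of 3.09 (SE 0.47, adjusted p = 0.0000005585). MI0001151 was higher as well, at 671 ± 185 against 283 ± 443 CPM (log2 1.71, SE 0.47, adjusted p = 0.00233). Both lay above the male median in 24 of 25 female libraries. MI0005470 was near absent in females, with 12 counts over 25 libraries and 0.124 ± 0.253 CPM, against 40.9 ± 103 CPM and a median of 2.24 CPM in males (log2 -7.49, SE 0.95, adjusted p = 0.00000002166). MI0005501 followed, at 0.153 ± 0.343 against 26.1 ± 68.8 CPM and a male median of 1.72 CPM (log2 -6.67, SE 0.85, adjusted p = 0.00000002241). Both male means rest on few libraries, with 495.7 CPM of MI0005470 and 338 CPM of MI0005501 in Q92_M replicate 2, and 19 and 22 of 27 males held any count. Another precursor held nearly the same counts as MI0005501, with a male mean of 25.9 CPM, so the call is uncertain as to which of them changed.

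Of 356 precursors, 172 passed, 79 higher and 93 lower in females, 4 of them in sets with identical values. Changes above 4 on the log2 scale numbered 17, all higher in males. Within the lane 5 series 94 of 308 passed (60 higher, 34 lower) and within the lane 1 and 3 series 125 of 345 (54 higher, 71 lower). Of the 306 precursors tested in both, 60 were called in both with the same direction and 0 with opposite directions, against 10 higher and 6.11 lower for independent lists, and log2 changes across precursors correlated with r = 0.898. On RPKM with limma the split was 100 higher and 53 lower. Without the libraries above 5 on principal component 1, which leaves 24 females and 13 males, 126 passed (75 higher, 51 lower). Of these, 97 were also called in all libraries in the same direction, and 4 of the 23 precursors with a log2 change below -3 were still called. The component was computed from the same counts, so leaving out its high libraries can itself take away such calls.

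Precursors called between the sexes in 1 series were used to score each library of the other, as the mean of standardised log2 CPM signed by direction. In the lane 5 series the score was 0.407 to 0.738 in females and -0.716 to -0.0857 in males. In the lane 1 and 3 series, scored on 94 precursors, 17 females lay between 0.333 and 0.810 and 18 males between -1.03 and -0.138. The library labelled Q140_F replicate 2 scored -0.935 and that labelled Q140_M replicate 4 scored 0.506. These libraries held 19.5 and 690.1 CPM of MI0000553. Without both, 192 precursors passed between the sexes.

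**Figure D3:**
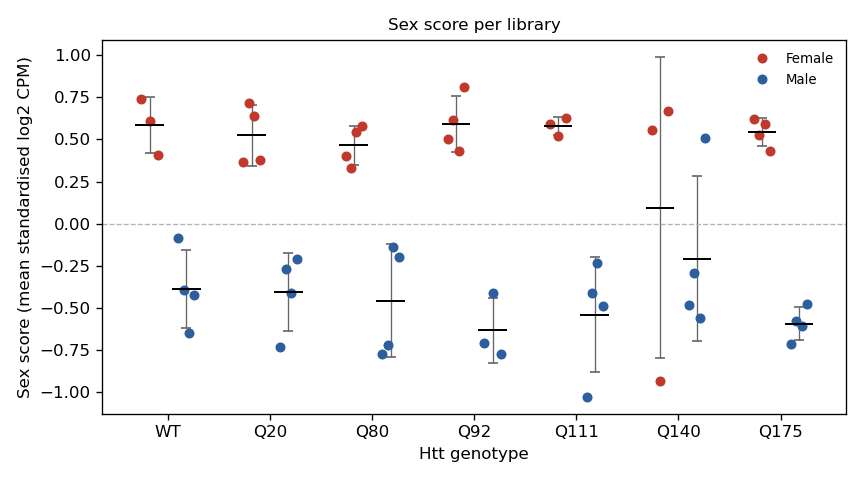
Sex score (vertical axis, mean standardised log2 CPM) of the 52 libraries by huntingtin genotype (horizontal axis) and sex as labelled; points are libraries, bars the mean and error bars 1 SD. All libraries lie on the side of 0 of their labelled sex except 1 female at -0.935 and 1 male at 0.506, both Q140.

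Whether the genotype changes differed between the sexes was tested with interaction terms. For Q175 against WT, edgeR gave 0 calls of 308, with 16 at an unadjusted p under 0.05, and DESeq2 and limma gave 0 each. The lowest p was that of MI0005513 (log2 difference -1.70, SE 0.44, adjusted p = 0.50), with 2.52 ± 1.29 CPM in Q175 females (SD, n = 4) and 4.77 ± 0.843 in WT females (SD, n = 3) but 6.18 ± 0.916 in Q175 males (SD, n = 4) and 3.52 ± 0.656 in WT males (SD, n = 4). Leaving out WT_M replicate 3 gave 4 calls. For repeat length, edgeR gave 0 calls of 345, with 18 at an unadjusted p under 0.05, and DESeq2 and limma gave 0 each; the lowest p was that of MI0014103 (log2 1.13 per 100 repeat units, SE 0.41, adjusted p = 0.828).

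Q20 was set against WT to ask what a repeat of normal length changed. MI0004658 stood at 102 ± 31.9 CPM in Q20 (SD, n = 8) and 4.27 ± 3.49 in WT (SD, n = 7), a log2 fold change of 4.72 (SE 0.40, adjusted p = 2.15e-13), and MI0021583 at 2670 ± 763 against 124 ± 41.4 CPM (log2 4.47, SE 0.40, adjusted p = 8.486e-13). MI0000231 was lower, at 32.5 ± 15.4 against 176 ± 96.7 CPM (log2 -2.42, SE 0.44, adjusted p = 0.0000149), and so was MI0004702, at 10.8 ± 4.77 against 27.5 ± 6.23 CPM (log2 -1.32, SE 0.20, adjusted p = 0.0000008247). Of 356 precursors, 122 passed, 71 higher and 51 lower in Q20. On RPKM with limma the split was 41 and 86 of 127, with the median of all precursors moved by -0.29. Genotype and library series cannot be told apart here, since no series holds both groups.

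Q175 against Q20 also crossed the series. MI0021583 was at 86.7 ± 72.1 CPM in Q175 (SD, n = 8; log2 -4.97, SE 0.39, adjusted p = 7.715e-15) and MI0021587 at 48.9 ± 25.9 against 1096 ± 269 CPM (log2 -4.49, SE 0.34, adjusted p = 3.268e-15). MI0000231 was higher in Q175, at 94.6 ± 45.7 CPM (log2 1.53, SE 0.42, adjusted p = 0.00373), as was MI0004702 at 22.2 ± 7.51 CPM (log2 1.04, SE 0.20, adjusted p = 0.00003771). In all 102 of 356 passed, 34 higher and 68 lower in Q175, and on RPKM with limma 72 higher and 44 lower. MI0021583 averaged 2471 CPM in Q111, 1874 in Q140, 2064 in Q80 and 1853 in Q92, all in the series of Q20.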

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

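The tests of the Q140 libraries and the lane, profile and genotype tests of principal component 1 were chosen after the result was seen. A library stood far from the others of its group, by a gap test at the 95% level, in 25 of 230 tests of groups of 4; chance alone gives about 1 in 20.

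Q20_M replicate 2 stood apart most often, with a score of 20.6 on principal component 1. It was high in MI0000248 (1273 CPM), MI0000224 (7711 CPM), MI0005470 (58.98 CPM) and MI0005501 (44.2 CPM). In MI0021587 it was low, at 657 CPM against 1130 to 1224 in the other Q20 males. WT_M replicate 1 was low in MI0014108 (27 CPM) and MI0000595 (43.4 CPM), and WT_M replicate 3 was high in MI0023705 (3.51 CPM), MI0005470 (5.16 CPM) and MI0005501 (3.92 CPM). WT_M replicate 4 held 1028 CPM of MI0000170. Q175_F replicate 4 held 94.2 CPM of MI0000248, against 7.55 to 11.3 in the other Q175 females. Q111_M replicate 1 and Q92_F replicate 3 were high in MI0000224 (735 and 400.2 CPM). Q80_F replicate 2 was high in MI0000595 (74.0 CPM), MI0004133 (62.2 CPM) and MI0000820 (34.7 CPM). Q80_M replicate 2 was high in MI0014103 (16206 CPM) and low in MI0004658 (65.6 CPM). Q140_M replicate 4 held 22.2 CPM of MI0004702. Near the detection limit, Q20_F replicate 1 held 0.251 CPM of MI0023705 and 0.502 of MI0005501, Q20_F replicate 3 held 0.582 of MI0005470 and Q92_F replicate 3 held 0.300 of MI0005501.

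The libraries labelled Q140_F replicate 2 and Q140_M replicate 4 lay on the other side of the sex score, and were the only 2 of 37 in the lane 1 and 3 series to do so; 0 of 15 did in the lane 5 series. Dilution of the female library by RNA of another tissue would lower the miRNAs that tissue lacks; MI0000553 and MI0001151 lay 5.10 and 4.60 lower on the log2 scale than in the other Q140 females, while 172 precursors of at least 10 CPM that were not called between the sexes within the lane 5 series differed by a median of -0.102 (SD 1.04 over precursors) and the 60 higher in females there by -0.80. Scaling to library composition holds such a median near 0, and miRNAs of both tissues would not fall, so dilution stays open for the female library. It would not account for Q140_M replicate 4, which scored 0.506. An exchange of the 2 labels is a candidate explanation: it needs 1 library of each sex out of place, and both are there, in 1 genotype and 1 lane. Their library numbers are consecutive. The exchange was found and tested on the same data and remains a hypothesis. An unusual female and an unusual male remain open as biological alternatives and were not tested.

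Principal component 1 was high in 14 males and in the library labelled Q140_F replicate 2. Lane explained a share of 0.0167 of the variance of the score among males, which argues against the lane. RNA of 1 outside tissue, carried into some male samples, may be the source, and was examined in the 23 precursors with a log2 sex difference below -3. Their median pairwise correlation across males was 0.801, from 0.0769 to 0.99994. This lies below the 0.9 set for a single fixed profile and above the 0.5 set against it. The precursors were chosen for being higher in these same males, which can itself raise the correlation, so this test cannot decide. An earlier form of this test, which had argued against a single profile, was set aside after its result was seen because it grouped samples by the measured score. Genotype differences among the 19 lane 1 and 3 males had a permutation p of 0.283, so genotype stays open, as does outside tissue, which could not be named without miRNA names.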

How the results depend on the processing

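The fits without libraries above 5 on principal component 1, without 2 Q140 libraries and over all 52 libraries were chosen after the data were seen; the cause of a change was not tested unless fewer libraries show it. Counts between the sexes (124 to 200), Q20 against WT (89 to 145) and Q175 against Q20 (70 to 122) stayed within 1.5 times of the main count except in subsets: females alone gave 59 and 61 calls, and the lane 5 series alone gave 94 between the sexes. Interactions gave 0 under every alternative except 1 single omission.

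The other counts depended on the processing. For Q175 against WT (14), Q80 (5), Q92 (14) and Q140 (1) against Q20, and the slope (1), DESeq2's size factors in edgeR gave 6, 1, 7 and 5 with the slope at 1. DESeq2 gave 34 for Q175, 17 for Q140 and 6 for the slope. No filter gave 2 for Q175 and 0 for Q80, Q140 and the slope; the filter of 50 counts gave 0 for Q80, 8 for Q92 and 4 for Q140. Limma on RPKM gave 9 for Q80, 2 for Q92 and Q111 and 4 for Q140. Removing the 5 most abundant precursors gave 1 for Q175, 0 for Q80, 5 for Q140 and 0 for the slope. With 1 surrogate variable Q175 had 2, Q80 8 and Q92 1. Females alone gave 0 for Q175, Q80, Q92 and the slope but 8 for Q140, and males alone 1 for Q175 and 0 for Q80, Q92, Q140 and the slope. The 3 Q140 females include Q140_F replicate 2, on the male side of the sex score. The Q140 males include Q140_M replicate 4, on the female side. How far the Q140 counts by sex rest on these libraries was not tested. The lane as a covariate gave 0 for Q80 and the slope. The slope also gave 0 by rank of repeat length, without Q20 and in lane 1 alone, and without Q20 the slope of MI0004133 turned to 0.12. Without libraries above 5 on component 1, Q175 had 0, Q80 8, Q92 5, Q140 0 and the slope 2. Without the 2 Q140 libraries Q140 and the slope had 0, and over all 52 libraries Q175 had 8, all lower. In the 35 alternatives of genotype and slope with 0 calls, 11 to 101 precursors had an unadjusted p under 0.05.

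Replicate numbers run within a sex, and same-numbered libraries did not deviate together (mean correlation -0.00671 in the lane 5 series and -0.0498 in the lane 1 and 3 series), so they share only a number. The fit with a replicate block gave 0 for Q175, 2 for Q80, 3 for Q92, 3 for Q140 and 2 for the slope, and moved no other count by over 1.5 times.

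Leaving out 1 library gave 0 to 37 calls for Q175: 3 without Q175_F replicate 3, 35 without Q175_F replicate 4, 1 without Q175_M replicate 2, 9 without replicate 3 and 0 without replicate 4, 2 without WT_F replicate 1 and 0 without replicate 2, 37 without WT_M replicate 1 and 0 without replicate 2, 3 or 4. Q80 had 0 to 14, the latter without Q80_M replicate 2, and fell to 3 or fewer in 31 of 37 omissions, the exceptions being Q111_M replicate 3, Q140_F replicate 2 and Q20_F replicates 1, 3 and 4. Q92 had 1 to 18 and fell in 32 of 37, all but Q111_F replicate 1, Q140_F replicate 2, Q20_M replicate 2 and Q92_F replicates 2 and 4. Q140 had 0 to 6 and moved in 28 of 37, all but Q111_F replicates 2 and 3, Q111_M replicates 1 and 4, Q20_F replicates 1 and 3, Q80_M replicate 2 and Q92_F replicates 2 and 4. The slope had 2 without Q20_F replicate 4 or Q80_M replicate 3, and 0 without Q111_F replicate 1, Q140_F replicate 1 or 2, Q140_M replicate 3, Q20_F replicate 2 or 3, Q20_M replicate 1, 3 or 4, Q80_F replicate 2 or 3, Q92_F replicate 1 or Q92_M replicate 1. Q111 had 0 to 2, the latter without Q111_F replicate 2, and the Q175 interaction 0 to 4, the latter without WT_M replicate 3. Sex gave 160 to 183, Q20 against WT 109 to 132 and Q175 against Q20 96 to 115. The lists fixed beforehand gave no value, since no precursor has a name.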

Other observations

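The held-out WT test and the lane test were written before their results were seen. A further requirement, a gap larger than the SD over precursors, was added to the held-out WT test afterwards. It left the reading of that test unchanged. The 122 precursors between Q20 and WT libraries may reflect the library series, the knock-in allele or the lane. If carrying a knock-in allele of any length were the cause, Q175 would move the same precursors against WT. For this, 4 WT libraries were used to call 86 precursors and the other 3 WT libraries were held out. Against the held-out libraries, the median Q175 change in the Q20 direction was 0.163 (SD 0.31 over precursors). The median Q20 change was 0.837, a ratio of 0.194, and it was 0.810 against the held-out libraries. These values argue against a knock-in allele of any length as the whole cause. In Q175, 62 of the 86 had the same sign, so a shared part stays open. Each genotype of the lane 1 and 3 series differed from WT in 101 to 143 precursors, and Q175 in 8 in the same fit. Lanes 1 and 3 within that series differed in 34 of 345 precursors, 19 of them among the 122, so lane stays open as a part, and the series itself cannot be told apart from genotype.

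Other splits of the same libraries within sex, 100 for each comparison with the real one included, tested whether chance could give as many calls. Few splits gave as many calls for Q175 against WT, where 1 of 100, the real one, gave as many as 14 and the highest other gave 0. The same held for Q80 against Q20 (1 of 100, real 5, highest other 2) and Q92 against Q20 (2 of 100, real 14, highest other 55). These splits were not balanced over lanes, and the lane as a covariate left 0 calls for Q80. Only the real split gave as many for sex, shuffled within genotype (1 of 100, real 172, highest other 42). This was also so for Q20 against WT (1 of 100, real 122, highest other 54) and Q175 against Q20 (1 of 100, real 102, highest other 28). The shares were not adjusted for the number of comparisons, and 100 splits are too few to exclude chance. More splits reached the real value for Q140 against Q20 (12 of 100, real 1, highest other 43) and the slope (15 of 100, real 1, highest other 54). The correlation of Q175 changes with slopes was reached in 19 of 100 (real 0.479, highest other 0.733), so for these results chance could give as much. With 0 calls, all 100 splits gave as many for Q111 (highest other 1), the Q175 interaction (highest other 5) and the repeat length interaction (highest other 45). For Q92, Q140 and the slope a split gave several times the real count, and for the repeat length interaction 45 against 0, which points to a structure of the samples beyond genotype; what that structure is was not tested.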
